A study of Mus musculus with 6 samples.

How the data were processed

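Bulk RNA sequencing was done on 6 samples of sorted mouse blood monocytes, 3 from mice with myocardial infarction and 3 from sham-operated mice, all taken on day 7 after surgery. Per the labels' protocols, blood was drawn from the retro-orbital sinus, red cells were lysed, CD45-positive, CD115-positive, Ly6C-high cells were sorted, and total RNA was extracted with TRIzol before library preparation. The deposited files hold whole-number read counts per gene symbol for each sample. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.1.0, HTSeq 0.11.2, R 3.2.0 and DESeq2 1.22.2 were used with genome build mm10; the notes name no role or order for them. The annotation, the strand setting and any filters of the authors are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner could not be told apart. Reads shared by near-identical genes could be divided or dropped by the counting, which makes values of gene families (Ly6, Klra, Gbp and immunity-related GTPases, Ifitm, stefins, haemoglobins) uncertain. A deposited table of the whole series holds the same counts and was not used.

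Groups and replicate numbers came from the sample titles. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 21.7 to 90.9, Pearson correlation of log CPM from 0.981 to 0.988), so none was counted as a duplicate. Library totals were 32570074, 34392989 and 34473974 counts for sham 1 to 3 and 33719575, 32061943 and 32639583 for MI 1 to 3. The common biological coefficient of variation was 0.139. Each library's lower limit was taken as 3 counts.

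Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 13889 genes and removed 0.0488% of the counts. Libraries were scaled by the trimmed mean of M-values (TMM), and MI was compared with sham by edgeR's quasi-likelihood F test with no other term. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are MI over sham on the log2 scale; their SE is the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalised and were computed here from the deposited counts, with SD over the 3 libraries of a group. For genes with 1 to 3 counts in a group, the ratio of summed counts was scaled to library size and given with an exact 95% interval from the binomial distribution, which covers counting error only. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 32 lists that had at least 5 tested members. Of 34 lists written, those for hepatocytes and cardiomyocytes had fewer. Members past the threshold were counted over all genes and adjusted over the list alone. Listed together, 19 genes belong to 2 lists each, Mmp8, Mmp9 and Csf3r among them. With a correlation estimated for each list, camera called 1 of the 20 lists it called with the preset value. The share of counts on each marker list was compared by an exact two-sided permutation test; 2 of the 20 sets, of granule and calprotectin genes, were added after the data were seen.

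The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the genes of the sort gate and of the series title, and the 12 higher and 12 lower genes with the lowest p whose MI and sham values did not overlap, leaving out predicted genes and segments of antibody and T cell receptor genes, histones and ribosomal proteins. Families such as Ly6 and Klra were not left out. It also took up to 4 members with the lowest p from each list that was called or held a called gene, and up to 2 from each other list. Other genes, such as further members of a list, were named after their values were seen. Gene positions came from GENCODE annotation of the same mouse build, matched by symbol.

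The test was tried on simulated counts for the MI and sham comparison of 13889 genes. It recovered 46.3% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 9 false calls among 154. A planted list changed 1.3-fold was found, and 0 of 33 unchanged lists were called. The simulated genes varied independently, so this did not test lists whose members vary together. In the data the estimated correlation was 0.939 for the erythroid list and 0.484 for the neutrophil list.

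Alternatives covered size factors of DESeq2 in place of TMM, no filter on low counts, a filter of at least 50 counts in 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, a 2-fold minimum, an unadjusted p, an estimated correlation or fry for the lists, and shares without the 10 most abundant genes. DESeq2 gave no adjusted p for 6121 genes. The low-count filter was rerun with each library left out, so 14216 to 14248 genes were tested there and list members could change. Alternatives chosen after seeing the data were a correction of each library's loess trend on transcript length and GC content (94.0% of tested genes had both), removal of erythroid genes, and removal of sham 3 together with MI 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.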

Results

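Gene expression was measured by bulk RNA sequencing in blood monocytes of mice on a diet that produces non-alcoholic steatohepatitis, an inflammatory fatty liver disease. Male C57BL mice received a choline-deficient, amino-acid-defined high-fat diet for 4 weeks. They had either a myocardial infarction (MI), made by tying off the left anterior descending coronary artery, or a sham operation. Blood cells that stained for CD45, CD115 and a high level of Ly6C, the surface pattern of classical inflammatory monocytes, were sorted on day 7 after surgery. There were 3 MI and 3 sham libraries. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Total gene counts per library ranged from 32061943 in MI 2 to 34473974 in sham 3, and 21031 of the 21630 listed genes had at least 1 count. At this depth a count of 0 in a library allowed a level of up to 0.0870 to 0.0936 CPM (counts scaled to library size), an upper limit that covers counting error only.

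The series has one contrast, MI against sham, and asks what an infarction changes in the circulating monocytes of mice with diet-induced liver disease. The genes with the lowest p were lower after MI. Ngp, a neutrophilic granule protein, stood at 17.4 ± 5.48 CPM in MI and 320 ± 80.9 CPM in sham (SD, n = 3), a log2 fold change of -4.2 ± 0.24 (SE). Ltf, the iron-binding granule protein lactotransferrin, fell from 208 ± 61.9 to 8.83 ± 4.49 CPM. Prok2, a secreted chemokine-like peptide, had 2047 counts in the 3 sham libraries and 1 count in the 3 MI libraries, a ratio of 1986 after scaling to depth (95% counting interval 356 to 78486). Lipg, endothelial lipase, had 1030 counts against 2 (ratio 500, interval 138 to 4132), and Nos2, the inducible nitric oxide synthase, 466 against 2 (ratio 226, interval 62.2 to 1872). Predicted genes aside, the higher genes with the lowest p were Chac1, a glutathione-degrading enzyme, with a log2 fold change of 2.11 ± 0.26, Eef2k, the kinase of translation elongation factor 2 (0.84 ± 0.10), Sema7a, a membrane-anchored semaphorin (1.41 ± 0.19), and the scavenger receptor gene Stab1 (1.58 ± 0.21).

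Of 13889 genes tested with edgeR's quasi-likelihood test, 81 were higher and 218 lower in MI at a Benjamini-Hochberg adjusted p under 0.05. A change of at least 2-fold was estimated for 34 of the higher and 97 of the lower genes. In all 299 the 3 MI values lay outside the range of the 3 sham values, which a call with 3 against 3 nearly requires. Over all tested genes this held for 22.1%, where chance gives 10% on average. Genes vary together, so the share can stray far from 10%, and the excess was not tested. The 12 higher and 12 lower genes taken by the fixed rule kept their call whichever library was left out, as did 20 of the 81 higher and 88 of the 218 lower genes. The counts themselves moved: they were 41 higher and 139 lower without sham 1, 38 and 124 without sham 2, 35 and 135 without MI 2, and 41 and 97 without MI 3. Without MI 1 they were 71 and 182, and without sham 3 they rose to 94 and 282.

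**Figure D1:**
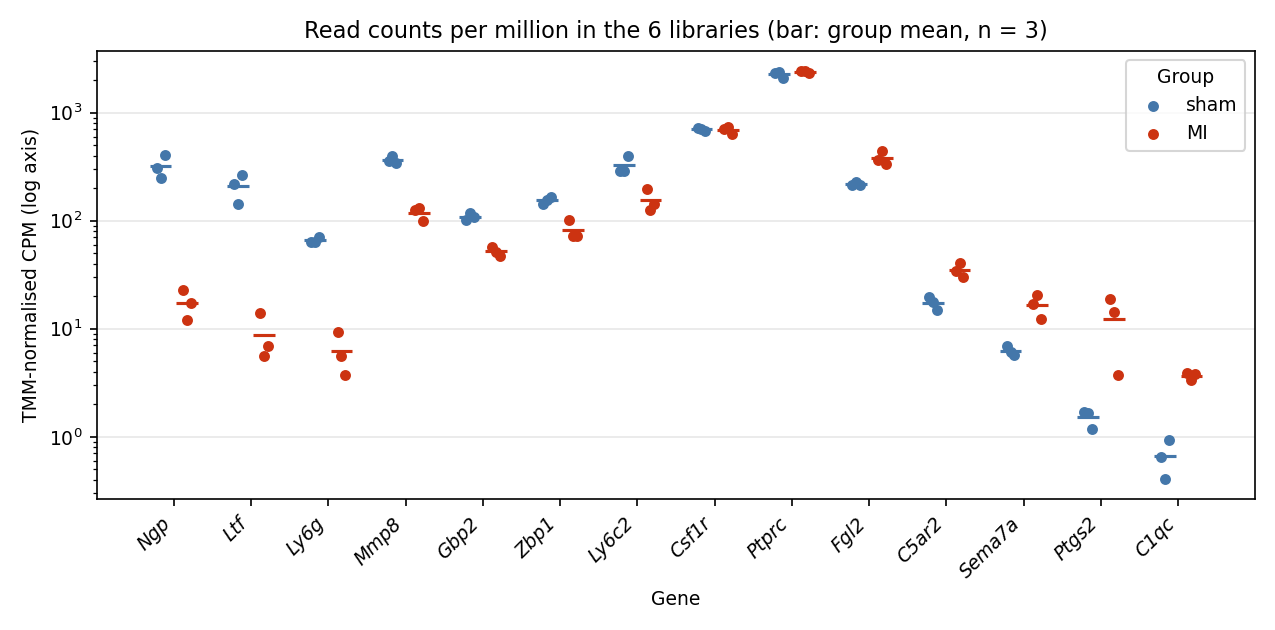
Normalised read counts in the 6 libraries for 14 genes, as CPM on a log axis. Each point is 1 library, blue for sham and red for MI, and the bar is the mean of 3 libraries. Ngp, Ltf and Ly6g stood over 10-fold lower in MI than in sham on average, while Csf1r and Ptprc overlapped between the groups.

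The surface markers of the sort gave different results at the transcript level. Csf1r, which encodes CD115, was at 696 ± 55.1 CPM in MI and 699 ± 15.4 CPM in sham, and Ptprc, which encodes CD45, at 2391 ± 42.6 and 2267 ± 140 CPM (SD, n = 3). Neither difference exceeded the spread between libraries, with edgeR adjusted p = 0.988 and 0.752. Ly6c2, a gene of the Ly6C antigen by which the cells were gated, fell from 324 ± 62.8 to 155 ± 36.1 CPM, a log2 fold change of -1.06 ± 0.17 (edgeR adjusted p = 0.00804). Without MI 3 the log2 fold change was -1.0 and the edgeR adjusted p was 0.0676. Ly6c2 belongs to a family of near-identical genes, so its reads may be shared with relatives. Postn, which encodes the matrix protein periostin named in the series title, had 1 count in all 6 libraries and was not tested; no difference was detectable at this depth.

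In the fixed list of classical monocyte genes, 5 of 18 members fell and none rose, and 11 fell when adjusted over the list alone. Mmp8, neutrophil collagenase, fell from 366 ± 27.0 to 118 ± 16 CPM (SD, n = 3), Cd177, a surface glycoprotein of granulocytes, had a log2 fold change of -1.07, and Chil3, a chitinase-like secreted protein, of -0.91. These 3 were called whichever library was left out. Mmp8 and Cd177 are also expressed by neutrophils, whose list fell further (median -1.35, 11 of 17 members lower). The chemokine receptor gene Ccr2 was at 356 against 425 CPM and did not pass the test. The list median was -0.48 on the log2 scale (camera adjusted p = 3.39e-16; adjusted p = 0.147 with an estimated correlation), and -0.32 without sham 3. Markers of nonclassical monocytes, the patrolling Ly6C-low subset, had a median of 0.21 with 1 of 17 members higher, and 2 when adjusted over the list alone (camera adjusted p = 0.00754; adjusted p = 0.334 with an estimated correlation). Without sham 2 or MI 2 that list was no longer called, at a camera adjusted p of 0.0505 and 0.0519.

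Neutrophil marker genes showed the largest shift of any list, with 11 of 17 lower and none higher; adjusted over the list alone, 15 were lower and 1 higher. Ly6g, a neutrophil surface antigen, fell from 65.8 ± 4.02 to 6.22 ± 2.91 CPM (SD, n = 3), Camp, the cathelicidin peptide, from 25.4 ± 8.70 to 1.83 ± 0.97 CPM, and Wfdc21 had a log2 fold change of -2.43. The calprotectin genes S100a8 and S100a9 fell from 2297 ± 254 to 801 ± 134 CPM and from 5003 ± 571 to 1923 ± 365 CPM. In contrast, Csf3r, the receptor for granulocyte colony-stimulating factor, was at 1876 ± 284 CPM in MI and 1405 ± 122 in sham, and Cxcr2, a chemokine receptor, at 409 against 519 CPM, both short of the threshold. The list median was -1.35 (camera adjusted p = 7.68e-60; adjusted p = 0.0602 with an estimated correlation), and 9 of the 11 calls stood whichever library was left out. Primary granule and progenitor genes were not called as a list (median -0.14, camera adjusted p = 0.0954; median -0.26 and adjusted p = 0.0519 without MI 2, median -0.08 without MI 3), and of its 11 members only Kit, a growth factor receptor of progenitors and mast cells, fell, from 12.1 to 3.89 CPM; adjusted over the list alone it was again the only one.

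Some interferon-inducible genes were lower in MI. In the list of interferon-gamma targets and guanylate-binding proteins, 10 of 18 members fell and none rose, and 16 fell when adjusted over the list alone. Gbp2, a guanylate-binding protein, was at 51.9 ± 5.18 CPM in MI and 109 ± 9.12 CPM in sham (SD, n = 3), Gbp6 had a log2 fold change of -0.97, and Igtp and Irgm2, 2 immunity-related GTPases, of -0.69 and -0.65. This was the only list called with an estimated correlation (median -0.46, camera adjusted p = 2.50e-24; adjusted p = 0.0262 with an estimated correlation). The list of type I interferon targets had 8 of 28 members lower and none higher, and 22 lower and 1 higher when adjusted over the list alone. Ifi44 fell from 4.83 to 0.73 CPM, Zbp1, a sensor of Z-form nucleic acids, from 154 to 81.7 CPM, and Ifit2 from 59.0 to 36.9 CPM. Its median was -0.57 (camera adjusted p = 1.25e-19; adjusted p = 0.334 with an estimated correlation). Of the calls in these lists, 6 of 10 and 3 of 8 stood whichever library was left out. The Gbp and immunity-related GTPase families hold close copies, and Igtp and Irgm2 overlap on chromosome 11, so reads may be shared between members.

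Genes of pathogen sensing fell in part. Of 22 genes for Toll-like receptors, inflammasomes and C-type lectin receptors, 5 were lower and none higher, and 6 were lower and 1 higher when adjusted over the list alone. Casp4, an inflammatory caspase, fell from 67.7 ± 4.2 to 37.3 ± 3.28 CPM (SD, n = 3) and was the only one of the 5 called whichever library was left out. Tlr4 was at 50.3 CPM in MI and 53.3 CPM in sham and did not pass the test. The list median was -0.18, and -0.12 without MI 3 (camera adjusted p = 8.95e-05; adjusted p = 0.334 with an estimated correlation). Among 21 genes of chemotaxis and adhesion the formyl peptide receptor genes Fpr1 and Fpr2 fell, also when adjusted over the list alone, with log2 fold changes of -0.75 and -0.80. The Fpr2 call was lost without MI 1 (edgeR adjusted p = 0.0617) and without MI 3 (0.0775), and the list was not called (median -0.02, and from -0.04 without MI 2 to 0.01 without MI 3; camera adjusted p = 0.250).

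C1qc, a chain of complement component C1q, was at 3.68 ± 0.30 CPM in MI and 0.664 ± 0.27 CPM in sham, and Stab1 at 6.28 ± 0.87 and 2.1 ± 0.25 CPM (SD, n = 3). Fgl2, a fibrinogen-like prothrombinase, rose from 218 ± 10.1 to 378 ± 54.8 CPM, and C5ar2, the second receptor for complement C5a, from 17.4 to 34.9 CPM. The receptor gene Chrm3 had a log2 fold change of 1.34 and the adaptor gene Cass4 of 0.76. Of the 17 genes of repair and phagocytosis, 4 rose and none fell, and 6 rose and 3 fell when adjusted over the list alone. The mean log2 fold change was 0.49 but the median 0.01 (camera adjusted p = 0.00951; adjusted p = 0.334 with an estimated correlation). With 1 library left out the median was 0.41 without sham 3, 0.27 without MI 3 and 0.16 without sham 1. It was 0.10 without sham 2, 0.03 without MI 1 and 0.01 without MI 2. The low-count filter was rerun each time and 5 members had not passed it before, so the members tested could change. Whether that or the missing library moved the median was not tested. The calls of C1qa and C1qb, chains of the same complex, were lost without sham 1 (edgeR adjusted p = 0.0670 and 0.0777), sham 2 (0.102 and 0.0858), MI 2 (0.141 and 0.0785) or MI 3 (0.144 and 0.120).

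Ptgs2, the inducible cyclooxygenase, had a log2 fold change of 3.03 ± 0.48, with 18.9, 14.4 and 3.72 CPM in the MI libraries and 1.51 ± 0.29 CPM in sham (SD, n = 3; edgeR adjusted p = 0.00793). It was the only one of 23 inflammatory NF-kB targets that rose, with none lower; adjusted over the list alone, 4 rose. With limma-voom its adjusted p was 0.138. Il1b, interleukin-1 beta, was at 715 ± 235 CPM in MI and 449 ± 32.9 CPM in sham and did not pass the test (edgeR adjusted p = 0.153; 0.00503 without MI 3). The list median was 0.15 (camera adjusted p = 0.00867; adjusted p = 0.334 with an estimated correlation), and the list call was lost without sham 1, MI 1 or MI 2 (camera adjusted p = 0.241, 0.267 and 0.209). Its median was 0.07 without MI 1, 0.10 without MI 3 and 0.09 without sham 3. Immediate early and stress genes had a median of 0.12 with no member of 22 past the threshold, and 5 higher when adjusted over the list alone (camera adjusted p = 0.00272; adjusted p = 0.442 with an estimated correlation). Without sham 1, MI 1 or MI 2 its camera adjusted p was 0.0511, 0.0822 and 0.0519. Without MI 3 the median was 0.25 (camera adjusted p = 2.56e-09), and Junb, Nr4a1, Atf3, Zfp36 and Dusp1 rose past the threshold (edgeR adjusted p = 0.00833, 0.0154, 0.0185, 0.0433 and 0.0496). It was 0.20 without sham 3 and 0.19 without MI 2.

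Genes of matrix and fibrosis moved both ways. Vegfa, vascular endothelial growth factor A, rose from 3.58 ± 0.29 to 8.39 ± 1.46 CPM, and Pdgfb, a platelet-derived growth factor chain, from 6.76 ± 0.37 to 12.7 ± 0.83 CPM (SD, n = 3). Timp2, a metalloproteinase inhibitor, fell from 60.5 ± 3.44 to 37.8 ± 3.73 CPM, and Mmp8 fell as given above. These 4 of 20 tested members were called whichever library was left out, and 2 were higher and 4 lower when adjusted over the list alone. The list was not called (camera adjusted p = 0.715, direction lower, against a median of 0.03 and a mean of 0.18), and its median was -0.18 without MI 2, 0.21 without MI 3, 0.06 without sham 1 and 0.01 without sham 2. The transforming growth factor gene Tgfb1 was at 340 CPM in MI and 308 CPM in sham and did not pass the test.

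**Figure D2:**
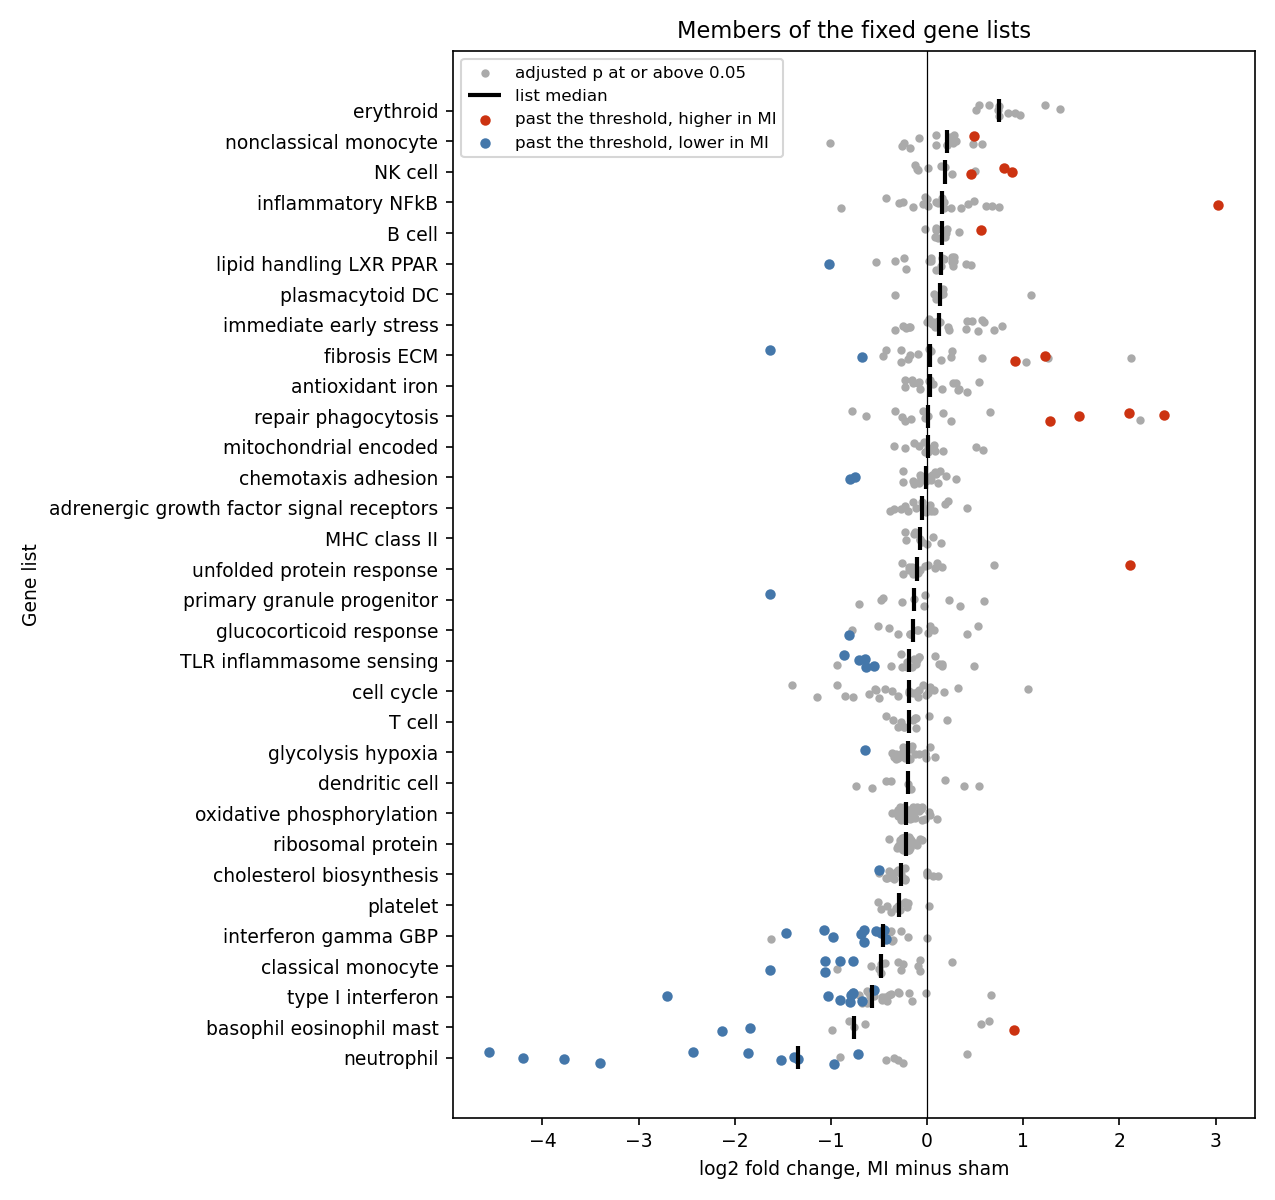
Log2 fold changes (MI minus sham) of the tested members of the 32 fixed gene lists. Each point is 1 gene, coloured where it passed the adjusted threshold, and the black bar is the list median. The neutrophil list has the lowest median (-1.35) and the erythroid list the highest (0.75).

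Metabolic lists moved by small amounts. Of 23 genes of glycolysis and hypoxia, only the lactate exporter gene Slc16a3 fell, from 212 to 135 CPM, and 7 fell when adjusted over the list alone; the median was -0.20 (camera adjusted p = 8.95e-05; adjusted p = 0.334 with an estimated correlation). Slc16a3 was not called without sham 1, sham 2, MI 1 or MI 3 (edgeR adjusted p = 0.0890, 0.138, 0.0917 and 0.1002). Of 19 cholesterol synthesis genes only Cyp51, lanosterol demethylase, fell (edgeR adjusted p = 0.04997, and 0.0535 to 0.217 with any 1 library left out), and 3 fell when adjusted over the list alone; the median was -0.27 (camera adjusted p = 0.000407; adjusted p = 0.147 with an estimated correlation). Ribosomal protein genes had a median of -0.22 with all 84 fold changes negative and none past the threshold, also over the list alone (camera adjusted p = 4.38e-09; adjusted p = 0.571 with an estimated correlation). Genes of oxidative phosphorylation had a median of -0.22 with 0 of 39 past the threshold, also over the list alone (camera adjusted p = 0.000407; adjusted p = 0.612 with an estimated correlation). Sham 3 stood apart here: its deviations from the mean of the libraries fell with transcript length (Spearman -0.475 across 13061 genes, which are not independent, against 0.0993 to 0.231 in the other libraries). It also had 6.63% of its counts on ribosomal protein genes, where the others had 4.68% to 5.11%. Without sham 3 the oxidative phosphorylation list was not called (median -0.05, camera adjusted p = 0.354), and the ribosomal median was -0.08. Cell cycle genes had a median of -0.19 and none of 27 past the threshold, also over the list alone (camera adjusted p = 0.0347; adjusted p = 0.334 with an estimated correlation). The cell cycle call was lost without sham 3 (median -0.10, camera adjusted p = 0.221) or MI 1 (0.149).

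Markers of other blood cells were present in all libraries. B cell transcripts were abundant for sorted monocytes: Cd79a, a chain of the B cell receptor, was at 951 ± 38.1 CPM in MI and 892 ± 44.1 CPM in sham (SD, n = 3), a level as high as that of Csf1r. Of the 10 B cell genes tested, only Fcer2a, the low-affinity IgE receptor CD23, rose, also over the list alone, with a log2 fold change of 0.56 (edgeR adjusted p = 0.0131). The Fcer2a call was lost without sham 2 (0.0597), MI 1 (0.0648) or MI 3 (0.0709). The list median was 0.15 (camera adjusted p = 0.00565; adjusted p = 0.334 with an estimated correlation). Of 11 natural killer cell genes, 3 rose and none fell, and 4 rose when adjusted over the list alone (median 0.18, and 0.10 without MI 3; camera adjusted p = 0.000465; adjusted p = 0.334 with an estimated correlation). Klra8, an activating natural killer receptor, rose from 21.9 to 40.4 CPM. The call of Ncr1, another such receptor, was lost without sham 1 (edgeR adjusted p = 0.0535), MI 1 (0.0675) or MI 3 (0.0984), and that of Klre1 without any 1 of 5 libraries, all but sham 3 (0.0835 to 0.229). Klra4 and Klri2, lectin-like receptor genes outside the list, had log2 fold changes of 0.78 and 0.74; the Klra genes are near-identical copies and their reads may be shared.

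T cell genes had a median of -0.19 with 0 of 12 past the threshold and 5 lower over the list alone (camera adjusted p = 0.00565, and 0.0519 without MI 2; adjusted p = 0.334 with an estimated correlation). For Lat, a signalling adaptor of T cells and platelets, the level was 68.0 CPM in MI and 91.3 CPM in sham. The platelet list had a median of -0.29 with 0 of 12 past the threshold, also over the list alone (camera adjusted p = 0.00128, and 0.157 without MI 1, where the median was -0.15; adjusted p = 0.442 with an estimated correlation). In the basophil, eosinophil and mast cell list 2 of 9 members fell and 1 rose, and 6 fell and 2 rose over the list alone. Mcpt8, a basophil protease, fell from 5.40 to 1.23 CPM and Fcer1a, the high-affinity IgE receptor chain, from 7.86 to 2.19 CPM. Siglecf, an eosinophil lectin, rose from 9.58 to 17.9 CPM, and this call was lost without any 1 library except sham 3 (edgeR adjusted p = 0.0890 to 0.146). The list median was -0.77 (camera adjusted p = 0.00111, and 0.118 without sham 3; adjusted p = 0.334 with an estimated correlation). Erythroid genes had a median of 0.75 with 0 of 11 past the threshold over all genes and 8 higher over the list alone (camera adjusted p = 5.75e-07; adjusted p = 0.334 with an estimated correlation). Alas2, the haem synthesis enzyme of red cell precursors, was at 1849 ± 731 CPM in MI and 946 ± 128 CPM in sham (SD, n = 3). Without MI 1 the list median was 1.03, and Alas2, Fech, Bpgm and Epb42 passed over all genes (edgeR adjusted p = 0.00553, 0.0133, 0.0226 and 0.0343). Without MI 2 the median was 0.48, and without sham 3 Bpgm passed (0.0375).

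The share of all counts on neutrophil markers was 0.693% ± 0.106 in MI and 1.298% ± 0.0913 in sham (SD, n = 3), and on classical monocyte genes 0.978% ± 0.0816 and 1.27% ± 0.0966. Haemoglobin genes held 4.04% ± 1.5 and 2.54% ± 0.720 of the counts, with 5.49% in MI 2. B cell markers held 0.584% and 0.512%, T cell markers 0.116% and 0.128%, natural killer markers 0.0539% and 0.0470%, and platelet markers 0.0584% and 0.0733%. Hepatocyte genes held 0.00939% and 0.0108% and cardiomyocyte genes 0.000218% and 0.000149%, and neither list had the 5 tested members that the list test needed. The mitochondrial share was 1.94% ± 0.135 and 1.91% ± 0.0796, and the 10 genes most abundant over all libraries held 7.29% ± 1.25 and 6.47% ± 0.987. In two-sided exact permutation tests of 20 such shares the smallest p that 3 against 3 libraries allow is 0.1, so none could pass. In 12 of the 20 sets, including neutrophil, classical monocyte, nonclassical monocyte, B cell, T cell, platelet, hepatocyte, cardiomyocyte and ribosomal genes, the exact p was that smallest 0.1 (0.167 after Benjamini-Hochberg adjustment), and the haemoglobin share had an exact p of 0.2.

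**Figure D3:**
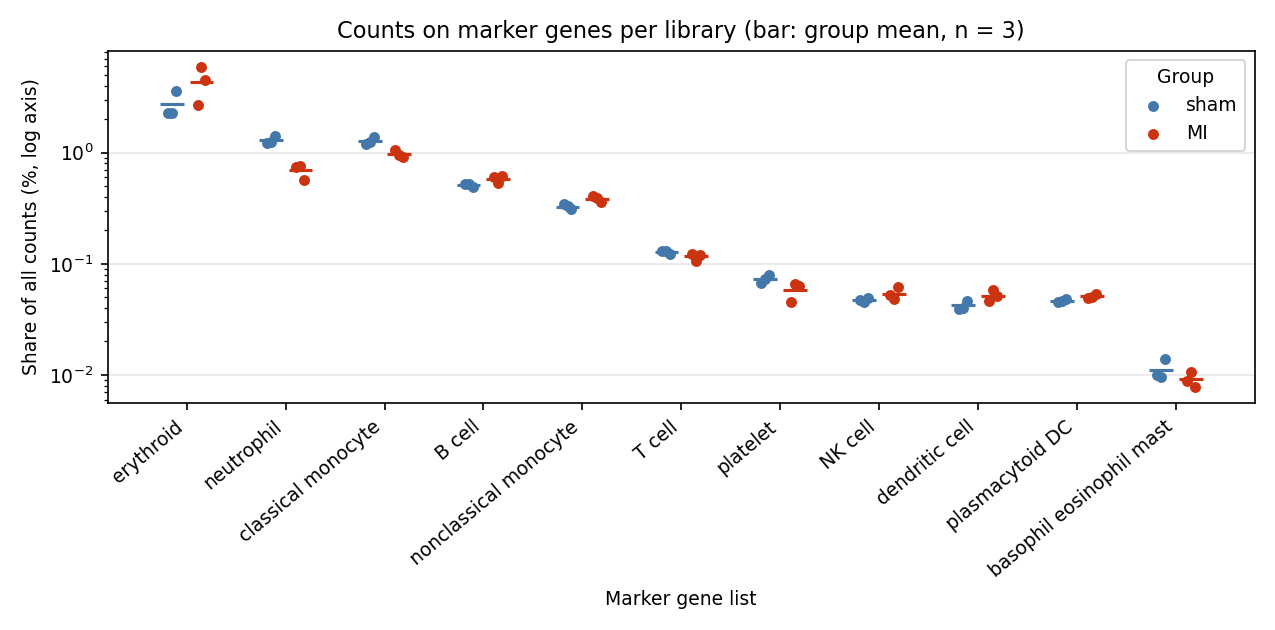
Share of all gene counts that fell on the marker genes of 11 cell types, in percent on a log axis. Each point is 1 library, blue for sham and red for MI, and the bar is the mean of 3 libraries. The neutrophil share lay between 0.571% and 0.756% in MI and between 1.23% and 1.40% in sham.

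Several lists showed no call. MHC class II genes had a median of -0.08 with 0 of 10 past the threshold, also over the list alone (camera adjusted p = 0.396; median -0.02 without sham 3 and -0.12 without sham 1), and H2-Eb1 was at 1161 CPM in MI and 1365 CPM in sham. Dendritic cell genes had a median of -0.20 over 9 members, and of -0.45 without MI 2, -0.40 without sham 1, -0.11 without MI 1, -0.07 without MI 3 and -0.05 without sham 3 (camera adjusted p = 0.716) and plasmacytoid dendritic cell genes of 0.14 over 7 members (0.167), with none past the threshold and, over the list alone, 1 higher and 1 lower in the former. Of 19 lipid handling genes only Fabp5, a fatty acid binding protein, fell, from 18.1 to 8.88 CPM, and 5 rose and 3 fell over the list alone (median 0.14, and 0.07 without MI 2 and 0.09 without sham 1; camera adjusted p = 0.575). Among 14 glucocorticoid response genes only Il1r2, the decoy receptor of interleukin-1, fell, from 80.6 to 46.1 CPM, and 1 rose and 2 fell over the list alone (median -0.14, and -0.01 without MI 3 and -0.06 without sham 3; camera adjusted p = 0.0954). In the unfolded protein response list only Chac1 rose of 18 members, and 2 over the list alone, while Xbp1 was at 140 CPM in MI and 167 CPM in sham; the median was -0.10 (0.03 without sham 3), the mean 0.08 and the camera direction higher (adjusted p = 0.777). Growth factor, cytokine and adrenergic receptor genes (17 members, median -0.05, camera adjusted p = 0.716), antioxidant and iron genes (18 members, median 0.03, 0.292) and mitochondrially encoded genes (13 members, median 0.00, 0.851) had no member past the threshold, over all genes or over the list alone. With 1 library left out their medians ran from -0.06 (MI 2) to 0.02 (MI 3), from -0.06 (MI 2) to 0.12 (sham 3) and from -0.05 (MI 3) to 0.07 (sham 3). DESeq2 called Csf3r of the receptor list and Slc11a1 of the antioxidant and iron list (adjusted p = 0.0210 and 0.0208).

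The genes named first lie on several chromosomes of the mouse genome build mm10, and all are protein-coding in the annotation. Ngp spans positions 110419747 to 110423012 and Ltf 111019271 to 111042767 on chromosome 9, where Mmp8 lies at 7558456 to 7568485. Prok2 is on chromosome 6 at 99711299 to 99726392, Lipg on chromosome 18 at 74939322 to 74961263, and Nos2 on chromosome 11 at 78920787 to 78960254. Ly6c2 at 75108158 to 75111970 and Ly6g at 75155240 to 75159126 are neighbours on chromosome 15. Chac1 is on chromosome 2 at 119351229 to 119354381, Stab1 on chromosome 14 at 31139013 to 31168641, Gbp2 on chromosome 3 at 142620602 to 142638008, and C1qc on chromosome 4 at 136889804 to 136893065.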

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

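Every called gene of the 299 kept its direction when any 1 library was left out. The MI and sham values of these genes did not overlap, so this was nearly certain in advance. No called named gene or list changed direction under any alternative tried on it. Lists were not rerun with DESeq2, limma-voom or the filter of at least 50 counts. Of 59 called named genes, 59 stayed called with DESeq2 or no filter, 58 with size factors and 54 with limma-voom. With the replicate number as a block 50 stayed called, and with 1 library left out 44 to 58. Named genes that were not called also gained a call, 19 with DESeq2, 25 with no filter and 21 with the length and GC correction. The 81 higher and 218 lower genes became 203 and 374 with no filter, 182 and 352 with DESeq2, 34 and 97 with a 2-fold minimum, and 172 and 195 with an unadjusted p and a 2-fold minimum. With 1 library left out they were 35 to 94 higher and 97 to 282 lower, and with the length and GC correction, chosen after seeing the data, 161 and 354 (80 and 215 shared). Without sham 3 and MI 2, also chosen afterwards, they were 84 and 259 (53 and 172 shared), and without erythroid genes 83 and 214. With the replicate number as a block they were 47 and 148 (45 and 144 shared). No pairing by number was seen: same-numbered libraries correlated at -0.0311, -0.0359 and -0.107 in their deviations from the group means. None correlated best with its own number. The deviations sum to 0 over the 3 libraries of a group and sham 3 stood apart, so this cannot exclude pairing. The labels do not say whether the numbers mark a shared animal, litter or day. The 7 higher and 13 lower lists became 0 and 1 with an estimated correlation and 0 and 4 with fry, and 4 to 7 and 10 to 13 with 1 library left out. The 4 lists called with fry were interferon-gamma targets, cholesterol synthesis, neutrophil and classical monocyte genes (fry adjusted p = 0.00135, 0.00867, 0.0106 and 0.0334). Of the 20 called lists, 19 stayed called with the length and GC correction and 18 without sham 3 and MI 2. Uncalled values near 0 changed sign: Csf1r was at 0.0012 with at least 50 counts and at -0.0531 to 0.0615 with 1 library left out. With 1 library left out, median or test direction changed for the lists of dendritic cells (-0.449 to -0.04995), chemotaxis and adhesion (-0.0407 to 0.0122), matrix and fibrosis (-0.181 to 0.208), mitochondrially encoded genes (-0.0536 to 0.0723), receptors (-0.0577 to 0.0183), unfolded protein response (-0.132 to 0.0253) and antioxidants and iron (-0.0627 to 0.118). The test direction also changed for dendritic cells under the length and GC correction (median -0.19) and for MHC class II without sham 3 and MI 2 (-0.000367). Apart from fewer samples or other genes tested, the cause was not tested. The alternative for normalised values was not run, since the files hold counts. Depth limits Postn and the genes with 1 to 3 counts in MI.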

Other observations

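Except for C4b and C1qc, the genes in the first 2 paragraphs were chosen after their values were seen, and so were the tests of neutrophil receptor genes and of B cell genes further on. Jchain, the joining chain of polymeric antibodies and a transcript of plasma cells, fell from 155 ± 42.8 CPM in sham to 37.3 ± 7.91 CPM in MI (SD, n = 3), a log2 fold change of -2.05 ± 0.21. B cell genes such as Cd79a and Ms4a1 did not pass the test (log2 fold changes of 0.09 and 0.08). The complement genes C4b and Cfb fell, with log2 fold changes of -1.99 and -1.52, while C1qc rose by 2.46. Anxa1, annexin A1, fell from 384 to 207 CPM and S100a6 from 291 to 146 CPM. Cebpa, a transcription factor of the myeloid lineage, fell from 92.0 to 55.4 CPM. These calls by edgeR's quasi-likelihood test stood whichever library was left out.

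Other single genes outside the fixed lists also fell. Ifitm1 went from 518 to 147 CPM, Ifitm6 from 185 to 80 CPM, Oas1g from 25.5 to 8.38 CPM, and Mov10 from 121 to 60.7 CPM. Wfdc17 went from 198 to 40.4 CPM and Chil1, a chitinase-like protein, from 149 to 46.2 CPM. Stfa2, Cstdc5 and Stfa1, members of a stefin gene cluster of close copies whose reads are hard to tell apart, had log2 fold changes of -3.58, -2.44 and -1.62. Cxcr1 fell from 17.3 to 5.57 CPM, whereas its relative Cxcr2 was at 519 and 409 CPM and did not pass the test.

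Granule protein genes such as Ngp, Ltf and Camp were lower in MI. A trend on transcript length and GC content between libraries was argued against: after its removal the neutrophil list median was still -1.16, against -1.35 before (camera adjusted p = 9.99e-65). A lower share of neutrophils in the MI libraries may contribute and stays open. The sort gated on CD115 and high Ly6C, but its purity was not measured here. The mean log2 CPM of Csf3r, Cxcr2 and Mxd1 differed by -0.0680 and that of S100a8 and S100a9 by -1.46, a gap of 1.39 where the SDs sum to 0.746, but these receptor genes were high in both groups and monocytes also express them, so a small loss could be hidden. An effect of MI on the monocytes themselves, or on the release of immature granulocytes, stays among the untested biological explanations.

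All 84 ribosomal protein genes had negative fold changes, with a median log2 fold change of -0.22, but none passed the threshold. With an estimated correlation the list was not called (camera adjusted p = 0.571). Sham 3 may account for part of the negative median: without it the median was -0.0787 and the camera adjusted p 0.00357. A length and GC trend is the other candidate explanation, since its removal gave a median of -0.0796 (camera adjusted p = 0.00147). The list was still called at the preset correlation in both cases, at a median nearer 0 than the -0.1 set as a bound. Neither explanation is therefore excluded. The 2 cannot be told apart, because the trend was strongest in sham 3. An effect of MI was not tested separately from these.

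B cell transcripts were abundant in libraries of sorted monocytes. Of the 10 tested B cell genes, 10 had a mean of at least 100 CPM in both groups, Cd79a (951 and 892 CPM) being the most abundant. This count restates the abundance and decides nothing about its source, so RNA of B cells in the libraries stays open as an explanation. Whether the gate on CD115 removed all B cells was not measured. The share of counts on B cell markers averaged 0.584% in MI and 0.512% in sham. It was higher in every MI library (0.537% to 0.615%) than in any sham library (0.487% to 0.527%).

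The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 299 genes and the highest other split 0, so 1 split of 10 reached the real count. For the fixed lists called by camera with the preset correlation, the real split gave 20 and the highest other 18, again 1 of 10. Every other split mixed MI and sham libraries and still called at least 8 lists. Such splits keep part of any MI and sham difference and add the rest to the spread within groups. Their gene and list counts therefore cannot show what would be called without an MI difference. A list call at the preset correlation does not by itself settle a difference, since camera with an estimated correlation called 1 of the 20 lists. In sham 1, the unnamed gene LOC118568312 held 1.06% of all counts, against 0.0542% to 0.105% in the other libraries.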
